A study of Homo sapiens with 17 samples.

How the data were processed

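The data were expression values from 17 microarrays of ARPE-19, a human retinal pigment epithelium (RPE) cell line, in 8 groups. The control group held 3 arrays and each of the 7 treated groups held 2. Per the labels' protocols, the cells were grown on membrane inserts until pigmented monolayers had formed, moved to serum-free medium and stimulated from the basolateral side for 48 h. RNA was extracted with a column kit and labelled with biotin by the manufacturer's standard protocol, per the labels' protocols. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1. The summarisation and normalization methods were not given in the sources used here.

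The authors deposited 1 table of log2 expression values with 33297 features, each summarising several probes on the array, and 17 columns, 1 for each array. That these are log2 values was taken from the values themselves, which ran from 1.183 to 14.446. Array medians lay between 6.743 and 6.933 and quartile ranges between 2.641 and 3.075, so the arrays were on a common scale without having identical distributions. No scaling or pseudocount was added. Features were named through a table of the array's annotation: 19460 had 1 gene symbol, 1754 had several and 12083 were not listed in it. Of the features with 1 symbol, 19429 matched the RefSeq gene table of assembly GRCh38.p14 by Entrez identifier and 0 symbols had to be updated. That table was used for names only. Features with several symbols named no gene, 24 features of chromosome Y genes and XIST were left out, and for the 768 genes with more than 1 feature the feature with the highest mean was kept, which gave 18394 genes. Genes were tested where they lay above the array median on at least 2 arrays, which left 12757. Detection calls and scanner intensities were not used here, and a check of RNA quality through the 3' and 5' control features was not analysed here. The number of arrays limits the precision.

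Groups and replicate numbers were taken from the labels. The labels do not say whether replicates were separate cultures, nor where the T cells came from, so p-values measure only the spread between these arrays, which may be technical. Correlations between replicates over all features lay between 0.969 and 0.994, and 0 arrays were identical to another. The SD over genes of an array's deviation from its group mean was 0.208 to 0.241 in the groups with T cells and 0.076 to 0.178 in the groups without.

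All 17 arrays were fitted together with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with a mean for each group, so that all groups shared 1 estimate of the spread per gene. A wide spread of a gene in 1 group thus widened its SE in every comparison, and a small spread in other groups narrowed it. There were 11 comparisons, all two-sided: IFNg, TNFa, IFNg+TNFa, T cells, and T cells with both antibodies, each against control; each antibody and both against T cells alone; the interaction of the cytokines and that of the antibodies; and T cells against IFNg+TNFa. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. The interaction is the effect of IFNg in the presence of TNFa minus its effect alone, on the log2 scale, and likewise for the antibodies. Errors given with log2 changes are limma's standard errors (SE).

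There were 29 gene lists fixed before the data were examined, among them CC and CXC chemokines, chemokine receptors, cytokines and growth factors, type I interferon response, TNF and NF-kB response, MHC class I, MHC class II, co-stimulatory and inhibitory ligands, complement, adhesion molecules, death receptors and apoptosis, RPE identity, epithelial junctions, extracellular matrix, matrix proteases, cell cycle, hypoxia and glycolysis, unfolded protein and integrated stress response, sterol biosynthesis, oxidative stress, IL-4 and IL-13 response, IL-17 response, markers of T cells, B cells, monocytes and endothelium, negative feedback regulators, and angiogenesis regulators. The result of 1 further list is not reported here. Some genes stand in several lists. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison, beside per-gene counts. Camera with an estimated correlation and fry were run as alternatives. Genes named in the text were chosen by a rule written before the data were examined: the genes with the largest rises and falls among those passing whose arrays did not overlap, the 3 passing members with the largest change of each list, 12 chemokines and the receptor genes of IFNg and TNFa. Names outside it are said to be chosen after their values were seen.

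Sets of genes raised at least 2-fold by a recombinant cytokine were carried into the antibody comparisons, which share no array with those that defined the sets. A gene counted as not raised by the other cytokine where it did not pass there with a rise of at least 2-fold. Smaller rises that passed could remain, so these sets are not specific to 1 cytokine. Fold changes of different comparisons were set against each other across genes. For comparisons sharing the controls, 100 simulations without any effect gave the covariance that shared controls alone produce. The per-gene step was tested on simulated data with 12757 genes. For IFNg against control it recovered 23.9% of the 1.5-fold, 58.2% of the 2-fold and 93.9% of the 4-fold changes, with 5.6% of its calls false. For anti-IFNg against T cells it recovered 11.9%, 62.7% and 100% of these, with 6.5% false, and for the cytokine interaction 6%, 22.4% and 84.8%, with 8.5% false. The simulated noise was independent between arrays, with 1 SD per gene in all groups. In the data the groups with T cells spread more, and their same-numbered arrays deviated together (correlations from 0.65 to 0.82). These rates therefore hold for the simulated setting and do not describe the antibody comparisons. As the SD was pooled over all groups, they do not describe the groups without T cells, which spread less, either. A single simulation was run for each comparison, with 66 or 67 changed genes at each fold and 7 or 8 false calls, so the rates are rough.

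Alternatives were no filter, a stricter filter at the array's 75th percentile, quantile normalization, centring on the array median, the mean over a gene's features, a fit of only the compared groups, array weights, a trended and robust variance prior, the replicate number as a block, and leaving out each array in turn. A term for the replicate number within the groups with T cells, and leaving out the arrays numbered 1 with T cells, were added after seeing the data.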

Results

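Gene expression was measured on 17 arrays of ARPE-19 cells, a line derived from human retinal pigment epithelium, the pigmented monolayer behind the retina that forms part of the blood-retina barrier. The study asked which chemokines RPE cells express after co-culture with activated T cells. The control group held 3 arrays of untreated cells. Recombinant interferon gamma (IFNg, 200 ng/ml), tumour necrosis factor alpha (TNFa, 40 ng/ml) or both were given to 3 groups of 2 arrays. T cells activated through CD3 and CD28 were added at 2.5 T cells per RPE cell in 4 further groups of 2 arrays, alone, with anti-IFNg (40 µg/ml), with anti-TNFa (118 µg/ml) or with both neutralising antibodies. All treatments lasted 48 h. Adjusted p-values are from limma with Benjamini-Hochberg adjustment. Several transcripts lay near the floor in control cells (CXCL10 at 3.93 ± 0.43 log2, SD, n = 3), where arrays compress fold changes, and others lay close to the table's maximum of 14.446. Among the latter were CXCL10 with IFNg+TNFa (13.30) or T cells (13.53), and CCL2 in all groups given TNFa or T cells (13.19 to 13.49). Differences can be compressed there too, so not passing does not show equal levels.

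IFNg raised genes of interferon signalling and antigen presentation. IDO1, which degrades tryptophan, rose 215-fold (log2 change 7.75 ± 0.2 SE, 5.19 ± 0.38 in controls, SD, n = 3, against 12.93 ± 0.01, n = 2, adjusted p = 1.45e-11). The guanylate-binding protein genes GBP5 and GBP4 rose 74.8-fold and 39.3-fold, and CTSS, which encodes the protease cathepsin S, rose 36.8-fold. CXCL10, a ligand of the chemokine receptor CXCR3, rose 81.5-fold (log2 change 6.35 ± 0.66 SE, adjusted p = 1.64e-05) and CXCL11, another CXCR3 ligand, 10.5-fold (adjusted p = 0.00529). CXCL9 changed by 0.78 ± 0.59 SE (adjusted p = 0.549) and CCL5 by 1.32 ± 0.53 SE (adjusted p = 0.144), neither passing. RGR and OCA2, which act in the visual cycle and in pigmentation, fell, with log2 changes of -2.70 and -1.32.

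Of the 35 tested members of the type I interferon list, 33 rose, 0 fell and 2 did not pass (35 adjusted over the list alone, median log2 change 2.68, camera adjusted p = 1.51e-52), among them OAS2 at 5.03 and RSAD2 at 4.93. In the MHC class I list 13 of 15 members rose (13 adjusted over the list alone, median 2.04, adjusted p = 1.62e-27), with PSMB9 at 3.72, TAP2 at 3.56 and TAP1 at 3.32, which process and transport peptides. In the MHC class II list 9 of 11 rose (10 adjusted over the list alone, median 1.99, adjusted p = 6.38e-14), HLA-DPA1 by 2.78. Of 16 co-stimulatory and inhibitory ligands 7 rose and 9 did not pass (7 adjusted over the list alone, median 0.70, adjusted p = 3.64e-08), with the PD-1 ligands CD274 at 3.65 and PDCD1LG2 at 2.69. Sterol biosynthesis genes rose in 19 of 25 cases (21 adjusted over the list alone, median 1.08, adjusted p = 1.03e-19), including HMGCS1 at 1.63. Hypoxia and glycolysis genes rose in 17 of 32 cases (20 adjusted over the list alone, median 0.53, adjusted p = 7.06e-14), and genes of the unfolded protein and integrated stress response in 16 of 29 (19 adjusted over the list alone, median 0.72, adjusted p = 1.32e-10, and adjusted p = 0.102 with an estimated correlation). Among 18 complement genes 7 rose, 3 fell and 8 did not pass (10 adjusted over the list alone, median 0.10, mean 0.52, adjusted p = 0.00601, and adjusted p = 0.102 with an estimated correlation), with CFB at 3.28 and SERPING1 at 2.91. Of 23 chemokine genes 4 rose and 19 did not pass (4 adjusted over the list alone, median 0.18, adjusted p = 0.00639, and adjusted p = 0.072 with an estimated correlation).

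In all, IFNg changed 1394 genes, 829 up and 565 down, of which 386 and 212 changed at least 2-fold. Leaving out control replicate 3 gave 928 genes and leaving out IFNg replicate 2 gave 605, where the lone array of the group is assumed to vary like the other groups. Array weights gave 2765.

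TNFa raised some chemokine genes and NF-kB target genes. CXCL8, which encodes the neutrophil attractant interleukin-8, rose 24.1-fold (log2 change 4.59 ± 0.21 SE, adjusted p = 7.28e-09) and CXCL1 5.06-fold (2.34 ± 0.3 SE, adjusted p = 6.45e-05). CCL2, a monocyte attractant, rose 6.06-fold, from 10.62 ± 0.15 (SD, n = 3) to 13.22 ± 0.05 (SD, n = 2, adjusted p = 9.2e-09), and CCL5, a T cell attractant, 10.1-fold (adjusted p = 0.000379). CXCL10 changed by 1.53 ± 0.66 SE (adjusted p = 0.12), CXCL9 by -0.38 ± 0.59 SE (adjusted p = 0.759), CCL7 by -0.15 ± 0.51 SE (adjusted p = 0.905) and CCL8 by -0.22 ± 0.2 SE (adjusted p = 0.535), none passing. Of 23 chemokine genes 6 rose, 0 fell and 17 did not pass (6 adjusted over the list alone, median 0.29, adjusted p = 0.004, and adjusted p = 0.0781 with an estimated correlation). PTX3, a secreted pattern recognition protein, rose 33.9-fold and TNFAIP3, an inhibitor of NF-kB signalling, 23.6-fold. RLBP1, which encodes the visual cycle protein CRALBP, and the melanocyte and RPE channel gene TRPM1 fell, with log2 changes of -2.34 and -3.42.

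Of 34 tested members of the TNF and NF-kB list, 29 rose and 5 did not pass (30 adjusted over the list alone, median 1.67, adjusted p = 2.27e-22). RPE identity genes fell in 19 of 31 cases, with 1 rising and 11 not passing (22 adjusted over the list alone, median -1.24, adjusted p = 9.94e-11). Cell cycle genes rose in 14 of 20 cases and 6 did not pass (16 adjusted over the list alone, median 1.18, adjusted p = 2.65e-10), with CCNE2 at 2.6, CDC6 at 2.12 and GINS2 at 1.79, which act at the start of DNA replication. The type I interferon list rose in 25 of 35 members (27 adjusted over the list alone, median 1.52, adjusted p = 6.12e-17), although adjusted p = 0.107 with an estimated correlation. MHC class I genes rose in 11 of 15 cases (12 adjusted over the list alone, median 1.32, adjusted p = 2.85e-11, and adjusted p = 0.077 with an estimated correlation). In the MHC class II list 2 genes rose, 4 fell and 5 did not pass (8 adjusted over the list alone, median -0.95, adjusted p = 0.232): CTSS rose by 4.85, while HLA-DMA (-2.13) and HLA-DPA1 (-2.23) fell, the latter call ending without TNFa replicate 1 (-1.94). Extracellular matrix genes rose in 15 of 33 cases and fell in 2 (18 adjusted over the list alone, median 0.35, adjusted p = 0.000195, and adjusted p = 0.377 with an estimated correlation), with CDH11 at 3.61, LOXL2 at 2.75 and CCN2 at 2.25.

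TNFa changed 2792 genes, 1539 up and 1253 down, with 579 and 522 changed at least 2-fold. Without TNFa replicate 1 there were 1530 genes and without TNFa replicate 2 there were 1432, while array weights gave 7070 and a fit of only the compared groups 5316.

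With IFNg and TNFa together, all 3 CXCR3 ligands rose above 100-fold. CXCL10 rose 659-fold (log2 change 9.36 ± 0.66 SE, adjusted p = 1.13e-07), CXCL11 198-fold (7.63 ± 0.7 SE) and CXCL9 192-fold (7.58 ± 0.59 SE, adjusted p = 3.4e-07). CCL5 rose 120-fold, the monocyte attractant CCL8 42.3-fold and CX3CL1, the membrane-bound ligand of CX3CR1, 28.9-fold. CXCL8 rose 2.23-fold (adjusted p = 0.000709). The pigment enzyme gene TYR, RLBP1 and TRPM1 fell, with log2 changes of -4.12, -4.03 and -4.57.

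**Figure D1:**
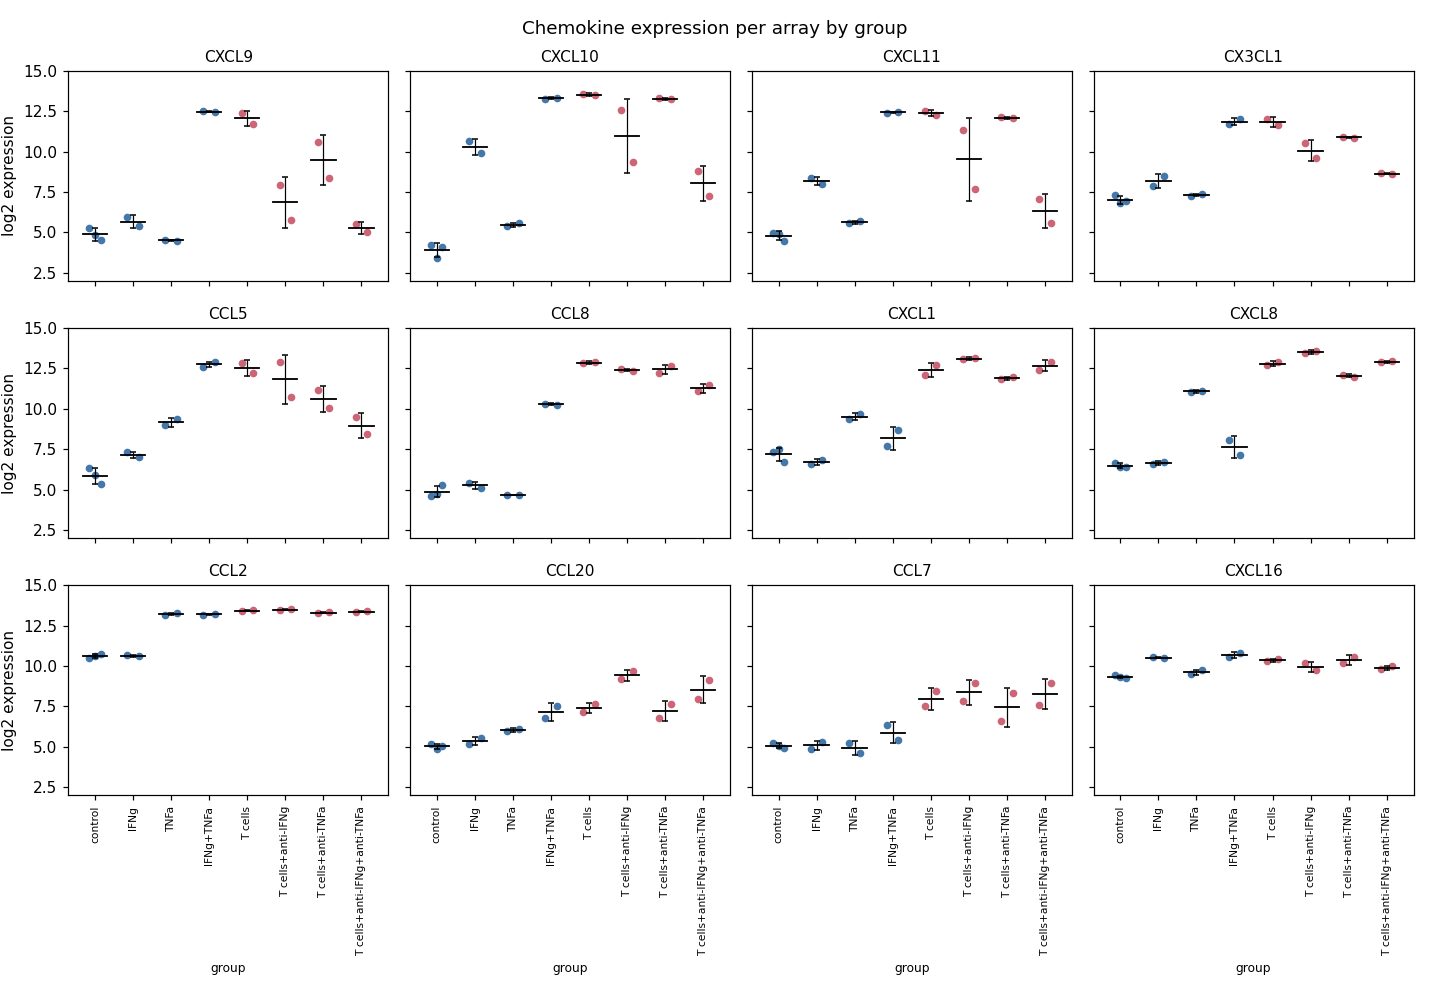
Log2 expression (y axis) of 12 chemokine genes in the 8 groups (x axis), with a point for each array, a bar at the group mean and whiskers of 1 SD. CXCL9 lay at 12.47 with IFNg+TNFa and at 4.50 with TNFa, while CCL2 lay between 13.19 and 13.49 in all groups given TNFa or T cells.

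All 35 tested members rose in the type I interferon list (35 adjusted over the list alone, median 3.71, adjusted p = 1.66e-37). The TNF and NF-kB list rose in 30 of 34 members (31 adjusted over the list alone, median 2.05, adjusted p = 1.16e-24). Of 23 chemokine genes 12 rose and 11 did not pass (12 adjusted over the list alone, median 0.99, adjusted p = 3.14e-07). Among 23 genes of death receptors, caspases and apoptosis 14 rose, 1 fell and 8 did not pass (18 adjusted over the list alone, median 0.71, adjusted p = 1.81e-07), with the death ligand gene TNFSF10 at 6.86 and CASP1 at 3.89. RPE identity genes fell in 19 of 31 cases and rose in 2 (22 adjusted over the list alone, median -0.96, adjusted p = 3.96e-09). Cell cycle genes had a median of 0.00, with 2 rising, 1 falling and 17 not passing (1 adjusted over the list alone, adjusted p = 0.851). Of 19 epithelial junction genes 4 rose, 4 fell and 11 did not pass (8 adjusted over the list alone, median -0.12, mean 0.01, camera direction down, adjusted p = 0.607), with CLDN1 at 2.90 and CLDN2 at -1.43. Matrix protease genes rose in 6 and fell in 9 of 25 cases (16 adjusted over the list alone, median -0.07, adjusted p = 0.242), with ADAMTS1 at -3.50 and TIMP4 at -3.12.

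IFNg+TNFa changed 3682 genes, 2015 up and 1667 down, 851 and 640 of them at least 2-fold. Without IFNg+TNFa replicate 1 there were 2436 genes and without replicate 2 there were 2260, while array weights gave 6724 and a fit of only the compared groups 5655.

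The interaction term asked whether IFNg acted differently in the presence of TNFa. CXCL9 stood 7.18 ± 0.88 SE above the sum of the separate log2 effects (adjusted p = 0.000345), CCL8 5.25 ± 0.3 SE (adjusted p = 3.71e-07) and CX3CL1 3.39 ± 0.38 SE (adjusted p = 0.000166). CXCL8 stood at -3.61 ± 0.31 SE (adjusted p = 2.64e-05): its mean was 11.07 ± 0.08 with TNFa (SD, n = 2) and 7.63 ± 0.66 with IFNg+TNFa (SD, n = 2). CXCL10 (1.48 ± 0.97 SE, adjusted p = 0.517), CXCL11 (3.40 ± 1.04 SE, adjusted p = 0.0786) and CCL5 (2.24 ± 0.78 SE, adjusted p = 0.128) did not pass. Their SEs draw on all groups, and these genes spread most with T cells and anti-IFNg, a group outside this comparison. CXCL11 had an SD of 2.56 there, against 0.01 to 0.27 in the groups compared. Not passing therefore does not show that the log2 effects of the cytokines simply added up for these genes. DKK1, an inhibitor of Wnt signalling, had the lowest passing term, -5.48 ± 1.05 SE, and its call ended without IFNg+TNFa replicate 2 (-4.58).

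Cell cycle genes had negative terms in 10 of 20 cases, with 0 positive and 10 not passing (13 adjusted over the list alone, median -0.98, adjusted p = 2.87e-13). MHC class I genes had negative terms in 9 of 15 cases (10 adjusted over the list alone, median -1.24, adjusted p = 2.67e-14, and adjusted p = 0.0833 with an estimated correlation). Each cytokine alone already raised most of this list, so an upper limit to these levels would by itself give negative terms. The terms do not show that the cytokines opposed each other for these genes. The interaction passed for 726 genes, 347 positive and 379 negative. Leaving out 1 array gave 470 without control replicate 2, 469 without control replicate 3, 309 without IFNg replicate 2, 328 without TNFa replicate 1, 309 without TNFa replicate 2 and 257 without IFNg+TNFa replicate 2. Array weights gave 2865 and a fit of only the compared groups 2059.

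Co-culture with activated T cells raised most of the chemokine genes tested. CXCL10 rose 775-fold (log2 change 9.60 ± 0.66 SE, adjusted p = 7.98e-08), CCL8 253-fold (7.98 ± 0.2 SE, adjusted p = 4.45e-12), CXCL11 193-fold, CXCL9 143-fold, CCL5 102-fold and CXCL8 79.9-fold. CXCL1 rose 37.8-fold, CX3CL1 28.2-fold, CCL7 7.47-fold, CCL2 7.04-fold and CCL20 5.18-fold. IL6, an inflammatory cytokine gene, rose 153-fold (7.26 ± 0.29 SE) and TNFAIP6, which binds hyaluronan, 303-fold (8.24 ± 0.19 SE, adjusted p = 2.08e-12). RLBP1 and the pigment transporter gene SLC45A2 fell, at log2 changes of -4.52 each, and so did TYR, at -4.68.

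Of 23 chemokine genes 18 rose, 0 fell and 5 did not pass (19 adjusted over the list alone, median 2.37, adjusted p = 6.24e-14). All 35 members rose in the type I interferon list (35 adjusted over the list alone, median 3.44, adjusted p = 3.17e-30), and 31 of 34 in the TNF and NF-kB list (31 adjusted over the list alone, median 2.78, adjusted p = 5.67e-25). IL-17 response genes rose in 12 of 16 cases (13 adjusted over the list alone, median 2.56, adjusted p = 2.77e-11), several of them also chemokines or NF-kB targets, with the acute phase gene SAA2 at 5.68. IL-4 and IL-13 response genes rose in 11 of 15 cases (11 adjusted over the list alone, median 1.22, adjusted p = 2.64e-06), with TGM2 at 5.04. TGM2 also rose with IFNg alone, by 2.22, so its rise is not particular to IL-4 or IL-13. Among 32 cytokine and growth factor genes 16 rose, 5 fell and 11 did not pass (22 adjusted over the list alone, median 0.69, adjusted p = 0.000787). Negative feedback regulators rose in 19 of 30 cases and fell in 6 (25 adjusted over the list alone, median 1.41, adjusted p = 5.32e-06, and adjusted p = 0.136 with an estimated correlation). Of 11 adhesion molecule genes 6 rose, 1 fell and 4 did not pass (7 adjusted over the list alone, median 0.50, adjusted p = 0.0147, and adjusted p = 0.132 with an estimated correlation), with ICAM1, a ligand of lymphocyte integrins, at 4.49. RPE identity genes fell in 23 of 31 cases, rose in 2 and did not pass in 6 (26 adjusted over the list alone, median -1.75, adjusted p = 1.87e-09). Angiogenesis regulators, a list that also holds the CXCR3 ligands, rose in 11 of 24 cases and fell in 2 (15 adjusted over the list alone, median 0.55, adjusted p = 0.000862).

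Markers of other cell types were measured beside these groups. Of 46 T cell markers 11 were tested, of which 3 rose and 8 did not pass (3 adjusted over the list alone, median 0.41, adjusted p = 0.0339, and adjusted p = 0.472 with an estimated correlation, median 0.17 and the call lost without T cells replicate 1). The 3 were IL7R at 6.03, GZMB at 0.69 and RAC2 at 0.62; the call of GZMB ended without control replicate 1 (0.65) or T cells replicate 2 (0.43), and that of RAC2 without control replicate 2 (0.62) or 3 (0.60) or T cells replicate 1 (0.60) or 2 (0.65). The medians of the other marker lists were 0.10 over 5 B cell genes (0 rose, 1 fell, 1 adjusted over the list alone, adjusted p = 0.843), 0.18 over 8 monocyte genes (1 rose, 1 fell, 2 adjusted over the list alone, adjusted p = 0.403) and 0.26 over 7 endothelial genes (2 rose, 1 fell, 3 adjusted over the list alone, adjusted p = 0.388). For B cells the mean was -0.14 and the camera direction down, against the positive median.

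T cells changed 4797 genes, 1976 up and 2821 down, with 826 and 1223 changed at least 2-fold. Fold changes of IFNg+TNFa and of T cells, each against the same controls, correlated across 12757 genes with Pearson's r = 0.85 and Spearman's rho = 0.71, genes not being independent replicates. Their covariance was 0.632, against 0.0208 in 100 simulations without any effect, in which r averaged 0.40. Both comparisons raised 1385 genes and lowered 1421, where independent lists would share 312.1 and 368.6, and 21 genes went opposite ways. The simulations reached a covariance of 0.0229 at most and shared 0 genes in either direction. Random spread of the shared controls thus gave little of the excess. The 3 controls could not be split into parts of at least 2 arrays, so a deviation common to all 3 was not tested.

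T cells and IFNg+TNFa were also compared directly. CXCL8 lay 35.9-fold higher with T cells (log2 difference 5.17 ± 0.23 SE, adjusted p = 3.02e-08), CXCL1 19.0-fold, IL6 14.6-fold and CCL8 5.98-fold. AQP9, a channel for water and glycerol, was 44.4-fold higher and LBP, which binds bacterial lipopolysaccharide, 12.6-fold. The CXCR3 ligands did not pass: CXCL10 differed by 0.23 ± 0.72 SE, CXCL11 by -0.04 ± 0.77 SE and CXCL9 by -0.42 ± 0.65 SE (adjusted p = 0.843, 0.978 and 0.683). Sterol biosynthesis genes were lower with T cells in 21 of 25 cases and 4 did not pass (22 adjusted over the list alone, median -1.28, adjusted p = 2.58e-19), with HMGCS1 at -2.76, DHCR7 at -1.81 and SQLE at -1.67. Chemokines were higher in 8 of 23 cases, with 0 lower (9 adjusted over the list alone, median 0.41, adjusted p = 2.81e-09), and IL-17 response genes in 9 of 16 (11 adjusted over the list alone, median 0.84, adjusted p = 2.72e-12). T cell markers passed in 0 of 11 cases (0 adjusted over the list alone, median 0.37, adjusted p = 0.0195, and adjusted p = 0.558 with an estimated correlation, median 0.24 and the call lost without T cells replicate 1). Of 6 chemokine receptor genes 3 were lower and 3 did not pass (4 adjusted over the list alone, median -1.01, adjusted p = 0.0839). The comparison passed for 1169 genes, 287 higher and 882 lower with T cells. It passed for 497 genes without IFNg+TNFa replicate 1, 233 without IFNg+TNFa replicate 2 and 460 without T cells replicate 1.

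**Figure D2:**
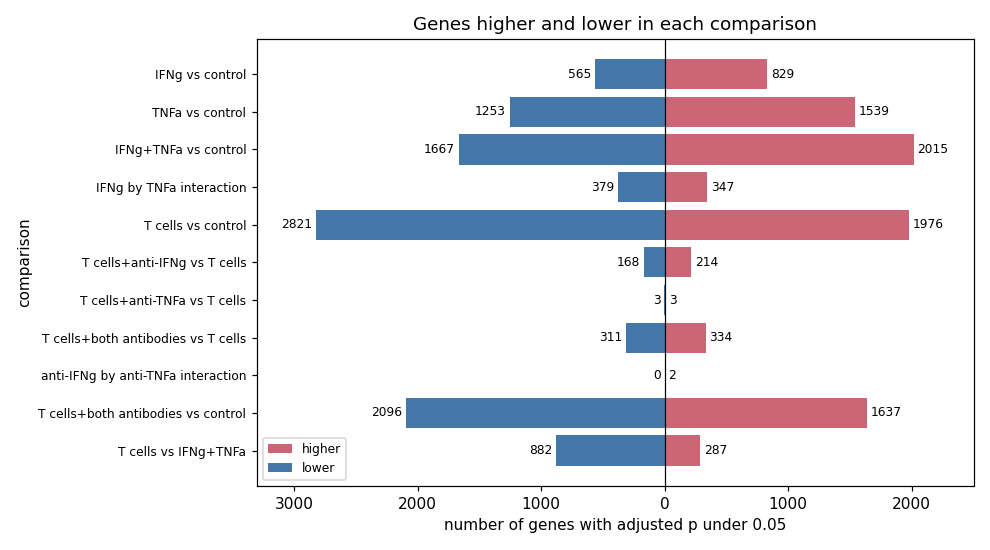
Number of genes with an adjusted p under 0.05 (x axis) in each of the 11 comparisons (y axis), with genes higher in the first-named group to the right and genes lower to the left. T cells lowered 2821 genes and raised 1976, while anti-TNFa changed 3 genes in each direction.

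Anti-IFNg, compared with T cells alone, lowered some chemokine genes and raised others. CXCL9 fell by 5.20 on the log2 scale (SE 0.65, adjusted p = 0.000676), with -4.42 between the arrays numbered 1 and -5.98 between those numbered 2. CX3CL1 fell by 1.77 (SE 0.28, adjusted p = 0.00279, -1.51 and -2.04). CXCL10 (-2.56 ± 0.72 SE, adjusted p = 0.079, -1 and -4.12) and CXCL11 (-2.86 ± 0.77 SE, adjusted p = 0.0638, -1.18 and -4.55) did not pass, their arrays with anti-IFNg lying far apart. CCL26, an eosinophil attractant, rose 9.68-fold (adjusted p = 2.33e-05, 3.97 and 2.58), CXCL6 4.32-fold (1.83 and 2.39) and CCL20 4.14-fold (2.04 and 2.05, the call was lost without T cells replicate 1 or anti-IFNg replicate 2, at 1.81 each). IL24 rose 20.4-fold, SERPINB4 15.9-fold and SERPINB3 10.4-fold, while LAMP3 fell by 4.26.

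In the type I interferon list 3 of 35 fell (19 adjusted over the list alone, median -0.63, adjusted p = 1.46e-13, and adjusted p = 0.317 with an estimated correlation). MHC class II genes fell in 1 of 11 cases, CIITA (8 adjusted over the list alone, median -0.89, adjusted p = 1.18e-07, and adjusted p = 0.104 with an estimated correlation); CIITA, the master regulator of this class, fell by 0.82, a call that was lost without T cells replicate 1 (-0.81), T cells replicate 2 (-0.82) or anti-IFNg replicate 2 (-0.55). IL-4 and IL-13 response genes rose in 5 of 15 cases (8 adjusted over the list alone, median 0.15, adjusted p = 0.0618). Of 23 chemokines 3 rose, 3 fell and 17 did not pass (10 adjusted over the list alone, median -0.17, adjusted p = 0.477). T cell markers had a median of -0.30 with 0 of 11 passing (0 adjusted over the list alone, adjusted p = 0.0705). Genes raised at least 2-fold by recombinant IFNg and not by TNFa numbered 183. Of these 34 fell, 1 rose and their median was -0.31 (camera adjusted p = 5.12e-18, and 0.0278 with an estimated correlation). The 203 genes raised by each cytokine had a median of -0.06, with 12 rising and 11 falling (adjusted p = 0.0166, and 0.506 with an estimated correlation). The 376 raised by TNFa and not by IFNg had a median of 0.15, with 25 rising and 9 falling (adjusted p = 0.00197, and 0.506 with an estimated correlation). Across 12757 genes, the changes with IFNg correlated with those removed by anti-IFNg at r = 0.21 (rho = 0.21), the comparisons sharing no array.

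Anti-IFNg changed 382 genes, 214 up and 168 down. There were 150 genes without T cells replicate 1, 218 without T cells replicate 2 and 147 without anti-IFNg replicate 2. Array weights gave 111 and a fit of only the compared groups 81. Same-numbered arrays deviated together in the groups with T cells (correlations from 0.65 to 0.82), and these fits leave that out. A term for the number in these groups, chosen after seeing the data, gave 2651 genes, and with it the falls of CXCL10 (adjusted p = 0.00549) and CXCL11 (adjusted p = 0.00357) passed, as did the rises of CXCL8 (0.71, adjusted p = 0.0312) and CXCL3 (0.82, adjusted p = 0.018), the last chosen after its values were seen.

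Anti-TNFa changed 6 genes, 0 in a fit of only the compared groups and 54 with the term for the number, chosen after seeing the data. PCP4 rose 4.13-fold (adjusted p = 0.00574, lost without T cells replicate 2, at 1.81), SLC1A7, a glutamate transporter gene, 3.40-fold and MEST 2.94-fold. SLAMF1, NDST4 and SERPINB7 fell, with log2 changes of -2.24, -2.36 and -2.96. SERPINB7 did not pass without T cells replicate 1 (-2.15), anti-TNFa replicate 1 (-2.89) or anti-TNFa replicate 2 (-3.03). CXCL9 changed by -2.56 ± 0.65 SE (adjusted p = 0.427, -1.78 and -3.33 by number), CCL5 by -1.91 ± 0.58 SE (adjusted p = 0.73, -1.67 and -2.15), CXCL8 by -0.75 ± 0.23 SE (adjusted p = 0.73, -0.58 and -0.91) and CCL2 by -0.13 ± 0.13 SE, none passing. With the term for the number the falls of CXCL9 (adjusted p = 0.00725), CCL5 (adjusted p = 0.0139) and, chosen after its values were seen, CCL3 (-0.90, adjusted p = 0.0131) passed, and CXCL8 did not (adjusted p = 0.195). Chemokines as a list lay lower with 0 of 23 passing (6 adjusted over the list alone, median -0.38, adjusted p = 8.47e-11), as did the TNF and NF-kB list with 0 of 34 (2 adjusted over the list alone, median -0.23, adjusted p = 8.47e-11, and adjusted p = 0.125 with an estimated correlation). RPE identity genes lay higher with 0 of 31 passing (0 adjusted over the list alone, median 0.20, adjusted p = 3.25e-08), and oxidative stress genes with 0 of 24 (2 adjusted over the list alone, median 0.26, adjusted p = 5.25e-08, and adjusted p = 0.243 with an estimated correlation, median 0.03 and the call lost without anti-TNFa replicate 2). At an unadjusted p under 0.05, anti-TNFa reached 390 of 12757 genes, fewer than the share of 0.05 that independent arrays give without any change. Same-numbered arrays with T cells deviated together, which this fit leaves out, so that share is not the right measure here. The count does not show that anti-TNFa had no effect. Its changes between arrays numbered 1 and between those numbered 2 correlated at 0.46 over genes. The 376 genes raised by recombinant TNFa and not by IFNg had a median of -0.08, with 0 passing (adjusted p = 0.000474, and adjusted p = 0.543 with an estimated correlation, median -0.15 and the call lost without anti-TNFa replicate 2, and median 0.01 without T cells replicate 2 or anti-TNFa replicate 1, where the call stayed). Across 12757 genes, the changes with TNFa correlated with those removed by anti-TNFa at r = 0.22 (rho = 0.19), the comparisons sharing no array.

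With both antibodies, the CXCR3 ligands lay far below their level with T cells alone. CXCL9 fell by 6.79 on the log2 scale (SE 0.65, adjusted p = 8.69e-05, -6.85 and -6.72 by number), CXCL11 fell by 6.06 (-5.44 and -6.69) and CXCL10 fell by 5.50 (SE 0.72, adjusted p = 0.000589, -4.80 and -6.20). CCL5 fell by 3.56 (-3.35 and -3.76), CX3CL1 fell by 3.20 (-3.37 and -3.02) and CCL8 fell by 1.58 (-1.73 and -1.44). CXCL8 (0.11 ± 0.23 SE, adjusted p = 0.923), CXCL1 (0.25 ± 0.32 SE, adjusted p = 0.86) and CCL2 (-0.07 ± 0.13 SE, adjusted p = 0.917) did not pass. CXCL6 rose 4.27-fold, SERPINB4 14.5-fold and TYR 4.53-fold.

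Type I interferon genes fell in 20 of 35 cases and 15 did not pass (28 adjusted over the list alone, median -0.96, adjusted p = 3.13e-27, and adjusted p = 0.0824 with an estimated correlation), with IFIT2 at -2.74. Chemokines rose in 2, fell in 8 and did not pass in 13 of 23 cases (13 adjusted over the list alone, median -0.23, adjusted p = 0.000557, and adjusted p = 0.0616 with an estimated correlation). Sterol biosynthesis genes rose in 9 of 25 cases (22 adjusted over the list alone, median 0.67, adjusted p = 3.24e-17, and adjusted p = 0.0616 with an estimated correlation), with HMGCS1 at 1.62 and MSMO1 at 1.32. RPE identity genes rose in 5 of 31 cases (8 adjusted over the list alone, median 0.37, adjusted p = 1.38e-05, and adjusted p = 0.0616 with an estimated correlation), with RDH10 at 1.60. Of the 183 genes raised at least 2-fold by IFNg and not by TNFa, 44 fell and 8 rose (median -0.36, camera adjusted p = 3.33e-18). Of the 203 raised by each cytokine 46 fell and 14 rose (median -0.24, adjusted p = 3.79e-08, and adjusted p = 0.212 with an estimated correlation). The 376 raised by TNFa and not by IFNg did not fall as a set, with 18 falling and 23 rising (median 0.07, camera adjusted p = 0.47). Across 12757 genes, the changes with IFNg+TNFa correlated with those removed by both antibodies at r = 0.49 (rho = 0.36), the comparisons sharing no array. The comparison passed for 645 genes, 334 up and 311 down. It passed for 267 genes without T cells replicate 1, 429 without T cells replicate 2 and 334 without replicate 2 of both antibodies. Array weights gave 142, a fit of only the compared groups 70, and the term for the number, chosen after seeing the data, 2228; with that term CXCL8, CXCL1 and CCL2 did not pass either, while the rise of CCL20 (1.15, adjusted p = 0.00336) and the fall of CCL18 (-0.45, adjusted p = 0.0328), the latter chosen after its values were seen, did. In the antibody interaction, the 203 raised by each cytokine had a median of -0.21 (camera adjusted p = 2.33e-12, and 0.182 with an estimated correlation). The 183 raised by IFNg and not by TNFa had -0.18 (7.67e-06, and 0.182). The 376 raised by TNFa and not by IFNg had -0.04 (0.353, and 0.81). CXCL10 (-2.69 ± 1.02 SE), CXCL11 (-2.90 ± 1.08 SE) and CXCL9 (0.97 ± 0.92 SE) did not pass. Their anti-IFNg arrays lay far apart, so this does not show that the log2 effects added up. The antibody interaction passed for 2 genes, NDST4 (2.50 ± 0.29 SE, adjusted p = 0.00874) and SLAMF1 (1.68 ± 0.24 SE, adjusted p = 0.0425). At an unadjusted p under 0.05 it reached 156 of 12757, fewer than the share of 0.05 that independent arrays give without any change. As this fit leaves out the shared deviation of same-numbered arrays, that share is not the right measure here either. In NDST4 and SLAMF1 the separate falls add up to more than the rise over control, so a floor at the control level would by itself give a positive term. The count ran from 0 to 3 as each array was left out: NDST4 did not pass without anti-IFNg replicate 1 (2.40) or anti-TNFa replicate 2 (2.36), and SLAMF1 did not pass without any of the 8 arrays with T cells (1.51 to 1.77) except T cells replicate 1 (1.85).

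Against untreated controls, cells with T cells and both antibodies still differed widely. IL6 lay 146-fold higher (log2 difference 7.19 ± 0.29 SE, adjusted p = 6.95e-10), CXCL8 86.5-fold, CCL8 84.6-fold, CXCL1 44.8-fold, CXCL10 17.1-fold and CCL20 11.5-fold. PTX3 was 156-fold and SAA2 95.3-fold higher. CXCL9 (0.38 ± 0.59 SE, adjusted p = 0.677) and CXCL11 (1.53 ± 0.7 SE, adjusted p = 0.123) did not pass. RLBP1 and TRPM1 lay lower, at log2 differences of -3.34 and -3.66. Chemokines were higher in 16 of 23 cases (17 adjusted over the list alone, median 2.16, adjusted p = 1.61e-12), IL-17 response genes in 15 of 16 (15 adjusted over the list alone, median 2.89, adjusted p = 6.91e-16) and IL-4 and IL-13 response genes in 11 of 15 (12 adjusted over the list alone, median 2.16, adjusted p = 1.28e-09). The TNF and NF-kB list was higher in 29 of 34 members (30 adjusted over the list alone, median 2.24, adjusted p = 4.28e-26). RPE identity genes were lower in 21 and higher in 4 of 31 cases (27 adjusted over the list alone, median -1.51, adjusted p = 4.4e-08). T cell markers rose in 2 of 11 cases, IL7R and RAC2 (2 adjusted over the list alone, median 0.11, adjusted p = 0.216), the call of RAC2 (0.63) ending without any of 4 arrays: control replicate 1 (0.66), 2 (0.63) or 3 (0.60), or replicate 1 of both antibodies (0.24). The comparison passed for 3733 genes, 1637 up and 2096 down, 664 and 816 of them at least 2-fold.

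**Figure D3:**
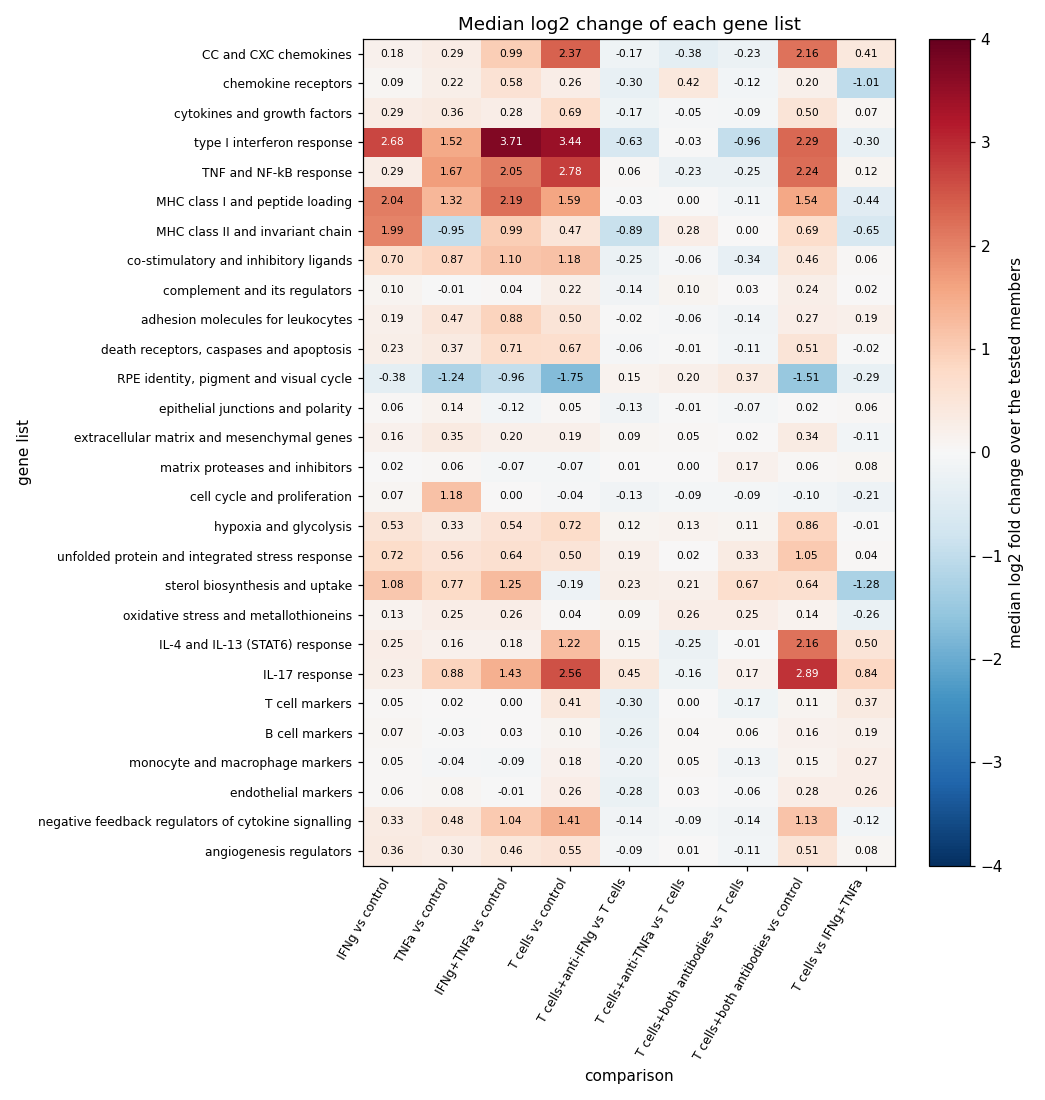
Median log2 change over the tested members of each gene list reported here (y axis) in the 9 comparisons that are not interactions (x axis), with red above 0 and blue below. The type I interferon list ran from 3.71 with IFNg+TNFa to -0.96 with both antibodies against T cells, and the RPE identity list was lowest, at -1.75, with T cells.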

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

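All tests in this part were laid down before their results were seen, and no explanation was tested for these values.

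The effect of IFNg depended on the presence of TNFa, by limma's test of the interaction, for 726 genes. Among the genes named by the rule, the terms were positive for CXCL9 (7.18), NDST4 (5.28), CCL8 (5.25), IGFBP5 (4.02) and CX3CL1 (3.39). They were negative for CXCL8 (-3.61), CLDN1 (-3.81), DTL (-3.89), AMTN (-4.69) and DKK1 (-5.48). The call of AMTN ended without IFNg replicate 2 (-3.68), TNFa replicate 2 (-4.37) or IFNg+TNFa replicate 2 (-3.91), and that of DKK1 without IFNg+TNFa replicate 2 (-4.58). CXCL9, CCL8 and NDST4 lay low in control cells, where arrays compress fold changes, and such compression of the separate effects can enlarge an interaction term.

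The antibody interaction passed for 2 genes, NDST4 (2.50) and SLAMF1 (1.68). NDST4 lay at 7.10 with T cells, 4.19 with anti-IFNg, 4.74 with anti-TNFa, 4.33 with both and 4.06 in control cells, and SLAMF1 at 7.61, 5.82, 5.38, 5.26 and 4.68. The separate falls of each gene add up to more than its rise over control, so a floor at the control level would by itself give a positive term, and the test does not show that the antibodies depended on each other.

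Features outside the comparisons of named genes also differed between T cells and control. Of 1178 tested features annotated to several genes, 402 changed, and of 4704 tested features without a listed gene, 661 changed, at a Benjamini-Hochberg adjusted p under 0.05 in limma.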

How the results depend on the processing

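The term for the replicate number within the groups with T cells, and leaving out the arrays numbered 1 with T cells, were chosen after seeing the data. The pseudocount alternative was not run, since the deposited values are log2 values. Low signal limits what can be seen for transcripts near the floor, and no alternative changes that.

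With array weights, 2765 genes changed with IFNg, 7070 with TNFa, 6724 with IFNg+TNFa and 2865 in the cytokine interaction, and 111 with anti-IFNg, 142 with both antibodies against T cells and 0 in the antibody interaction. Fitting only the compared groups gave 5316 genes for TNFa, 5655 for IFNg+TNFa, 2059 for the cytokine interaction, 81 for anti-IFNg, 0 for anti-TNFa (limma; 390 at an unadjusted p under 0.05 in the fit of all arrays), 70 for both antibodies and 0 for the antibody interaction. In both alternatives, by construction, the spread of the groups with T cells, which was larger, no longer counts in full for the groups without. In turn, the smaller spread of the groups without T cells no longer narrows the SEs of the antibody comparisons in full. The antibody counts as reported thus rest in part on that smaller spread. A fit of only the compared groups also has fewer arrays to estimate the spread. How far each of these lowered the antibody counts was not tested. Centring on the median gave 253 genes for anti-IFNg.

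The antibody interaction, 2 genes as reported, gave 1 with no filter, the stricter filter, quantile normalization, median centring or the replicate block, and 0 with the trended and robust prior or without the arrays numbered 1 (156 at an unadjusted p in the fit as reported). The other counts stayed within 1.5 times the reported ones under the filters, quantile normalization, the mean over features, the prior and the replicate block.

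Same-numbered arrays deviated together in the groups with T cells (correlations from 0.65 to 0.82 over 6 pairs) but not in those without (-0.22 to 0.22 over 6). The term for the number in the groups with T cells gave 2651 genes for anti-IFNg, 54 for anti-TNFa and 2228 for both antibodies against T cells. Leaving out the arrays numbered 1 with T cells gave 787 genes for anti-IFNg and 12 for anti-TNFa, but each group with T cells then held 1 array, so the spread came from the groups without T cells, where it was smaller, and these counts do not measure the effect of leaving the arrays out.

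With an estimated correlation, 91 of 146 list calls were lost. Among the sets raised by the cytokines, calls were lost with anti-IFNg for the TNFa set (0.15) and the genes raised by each (-0.06), with anti-TNFa for the IFNg set (0.08), the TNFa set (-0.08) and the genes raised by each (0.02), and with both antibodies for the genes raised by each (-0.24). The genes raised by each also lost their call with anti-TNFa without a fold minimum (0.02) and with the replicate block (0.02). Fry lost 28 list calls, no filter 4 and the replicate block 2. Correlations across genes moved from 0.85 to 0.83 with no filter for IFNg+TNFa against T cells, from 0.21 to 0.24 with quantile normalization for IFNg against anti-IFNg, and from -0.05 to -0.02 for TNFa against anti-IFNg. Over genes passing in either comparison they were 0.89 for IFNg+TNFa against T cells, 0.80 for IFNg+TNFa against both antibodies, and, against the change an antibody removed, 0.25 for IFNg, 0.34 for TNFa and 0.58 for IFNg+TNFa; fewer genes enter by construction.

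Leaving out each array in turn, the lone array of a group being assumed to vary like the other groups, gave 605 to 1390 genes for IFNg, 1432 to 2548 for TNFa, 2260 to 3343 for IFNg+TNFa, 257 to 885 for the cytokine interaction, 3414 to 4518 for T cells, 147 to 518 for anti-IFNg, 5 to 8 for anti-TNFa, 267 to 494 for both antibodies against T cells, 0 to 3 for the antibody interaction, 2500 to 4084 for both antibodies against control and 233 to 889 for T cells against IFNg+TNFa. Medians of the IFNg set ran from -0.36 to -0.24 with anti-IFNg, -0.03 to 0.20 with anti-TNFa and -0.50 to -0.29 with both. Those of the TNFa set ran from 0.06 to 0.21, -0.15 to 0.01 and -0.05 to 0.14. Those of the genes raised by each ran from -0.20 to 0.07, -0.09 to 0.16 and -0.34 to -0.13. Some of these medians changed sign while the direction of camera's test over the set stayed. That direction reversed in 5 cases, given with their medians: genes raised by each without anti-TNFa replicate 2 (-0.09), the TNFa set without replicate 2 of both antibodies (-0.05, a test that had not passed as reported, adjusted p = 0.47), extracellular matrix genes with anti-TNFa without T cells replicate 2 (-0.11) or anti-TNFa replicate 1 (-0.13, lowest, the highest being 0.31), and type I interferon genes in the antibody interaction without anti-IFNg replicate 1 (0.04, highest, the lowest being -0.82). With an array left out, 379 values of named genes lost their call, 2525 did not and 0 reversed; the cause was not tested.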

Other observations

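The tests of genes above each cytokine group, over all markers on the array, of 10 transcripts abundant in T cells, of genes under the filter and over all 851 genes raised by IFNg+TNFa were chosen after the result was seen, and for 3 of the other tests, all on T cell markers, the reading was changed after the values were seen, as said at each.

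With T cells, 3 of 11 tested T cell markers rose: IL7R (6.03), GZMB (0.69) and RAC2 (0.62). With both antibodies the median of the 11 was 0.11 against control; the bound of 0.2 set beforehand alone would have counted this against RNA of T cells in the harvested RPE, a reading withdrawn because the arrays lay at 0.52 and -0.13, each 0.33 from their mean. Over the 3 genes the median change with IFNg+TNFa was 0.18 of that with T cells, which the bound set beforehand alone would have counted against induction by these cytokines. That reading was withdrawn because IL7R reached 0.85, GZMB -0.04 and RAC2 0.20, and because the direct differences between T cells and IFNg+TNFa did not pass (adjusted p = 0.38, 0.0647 and 0.172). Over all 44 markers on the array the median change was 0.33 with T cells, 0.20 with both antibodies and -0.02 with IFNg+TNFa, which goes with T cell RNA more than with induction. But 33 of the 44 lay under the filter, where 5604 other genes had medians of 0.15, 0.13 and -0.04, and the arrays with both antibodies lay at 0.48 and -0.11. For IL7R alone, the rise with IFNg+TNFa was 5.15 in a group without T cells, so most of its rise did not need T cell RNA. GZMB (-0.03) and RAC2 (0.13) changed little with IFNg+TNFa. For the markers as a set, T cell RNA and induction cannot be told apart here. The 10 transcripts abundant in T cells, chosen after their values were seen, differed from control by 0.12 to 0.57 with T cells, none passing. They stood low, PTPRC at 3.72 in controls and 4.15 with T cells and CD3D at 5.54 and 5.95.

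Arrays numbered 1 and 2 differed in the groups with T cells, with an SD over genes of 0.399. Quantile normalization lowered it by 2.78%, to 0.387, which argues against the spread of signal as its main cause. Yet signal spread less on the array numbered 1 in each group with T cells. With T cells alone its quartiles lay at 5.518 and 8.169, against 5.366 and 8.312 on number 2. T cell markers lay 0.41 higher on arrays numbered 1 (0.22 to 0.61 in the 4 groups), above 98.7% of 10000 matched lists. After quantile normalization they lay 0.31 higher, so part of this difference went with the spread of signal. The bounds set beforehand alone would have read the 0.41 as a different amount of T cell RNA. That reading was withdrawn because 20 markers of other cell types also differed by 0.41, and 3 T cell markers, GZMB (-0.15), IL7R (-0.30) and LCP1 (-0.29, named after its values were seen), went the other way. The cause stays open, and separate cultures or T cell donors, which the labels do not give, were not tested.

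With both antibodies 1637 genes still lay above control, and their median log2 change with IFNg+TNFa was 0.77. Over 747 genes raised at least 2-fold by IFNg+TNFa and also raised with T cells, the median share of the T cell response kept was 0.73, and over all 851 raised at least 2-fold by IFNg+TNFa the ratio of medians was 0.70 (1.01 with both antibodies, 1.44 with T cells alone), which is consistent with incomplete neutralisation, although the comparisons share their controls and other signals could raise the same genes. Single genes went other ways: with both antibodies CXCL9 lay 0.38 and CXCL11 1.53 above control, neither passing, against 7.58 and 7.63 with IFNg+TNFa, while CXCL8 lay 6.44 above control, against 1.15 with IFNg+TNFa. Of the 1637 genes, 113 (6.9%) also lay above each group given recombinant cytokine. That share lay between the bounds that would have argued for or against other T cell signals or T cell RNA. For the 1637 genes as a whole this stays open. The 113 lay above what IFNg and TNFa reached at the doses given, which argues against incomplete neutralisation alone for these genes. CXCL8 lay at 12.91, against 11.07 with TNFa, and CCL8 at 11.28, against 10.28 with IFNg+TNFa, their highest cytokine groups. Other T cell signals and T cell RNA were not told apart. These 113 held 8 chemokines, 8 IL-17 response genes, 7 TNF and NF-kB response genes, 4 IL-4 and IL-13 response genes and 0 T cell markers, and included PTX3 (7.29), IL6 (7.19), SAA2 (6.57) and SERPINB4 (6.00 above control).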
